A study of Homo sapiens with 8 samples.

How the data were processed

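The samples were U2OS cells at early, mid and late G1 for ORCA ChIP-seq and U2OS cells of no stated stage for MeDIP-seq, each with an input. The submitters' processing notes name Trimmomatic and Bowtie 0.12.7, and the genome builds GRCh37 and hg19, which are the same assembly. For each of the 4 immunoprecipitated samples the authors deposited a list of peaks. The peak caller's version, its settings, the control library and the number of reads were not given in the sources used here. The peak names point to a caller of the MACS family. The name of the late list marks the caller with another number than the names of the early and mid lists. Whether this stands for another version, run or setting was not stated, so that the number of peaks is a product of the samples and of the calling together. Fewer reads or a stricter setting give a shorter list, and the length of a list is not a measure of binding alone.

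Besides the score, the other values in the deposited lists are the start and end of each peak. The starts were counted from 0 and are printed here from 1. The score in the deposited lists was taken as the caller's own score per peak. It was at least 50 in all 4 lists and reached 3100 in the ORCA lists, where 16 early, 16 mid and 10 late peaks shared the highest value. In the MeDIP list 5500 peaks had a score of at least that value, with a maximum of 3233. Scores were compared only within a list: to order its peaks, to compare medians between groups of its peaks or bins, and to find runs of narrow peaks with a score of 100 or more. The rank of a peak was its rank by score divided by the length of its list, with shared scores given their mean rank.

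Peaks on chromosomes 1 to 22 and X were used. This left 10666 of 10740 early, 10341 of 10382 mid, 1328 of 1347 late and 74497 of 75555 MeDIP peaks. No further filter was applied. A peak counted as overlapping when it shared at least 1 bp with a peak of the other list. Shares are given with 95% Wilson intervals, and differences between shares with Newcombe intervals. Both kinds cover counting error only, and neighbouring peaks are not independent. ORCA regions were made by merging overlapping peaks of the 3 ORCA lists.

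Each overlap was set beside 1000 random placements (seed 17). In the main setting each peak of a list kept its width and was placed at random on its own chromosome. Placements stayed between the first and last peak of all lists and outside stretches of more than 1 Mb with no peak in any list, since the sequence of the genome was not used here. This left 2523 Mb. In the alternative setting each peak was shifted by 50 to 500 kb in either direction. An overlap was called above chance when it exceeded all 1000 placements. These placements describe single lists and are no test between samples. The code was checked on simulated lists, which tests the counting and not the choice of placements: of 2666 overlaps planted in random lists of the early length, 2666 were found, as were 332 of 332 at the late length, and none of 20 random lists per comparison was called. The mean fold of these random lists was 0.993, 0.971 and 0.993.

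Peak density was the number of peak midpoints per 1 Mb bin over 2771 bins, and Pearson and Spearman correlations were computed across bins. Their intervals came from 1000 resamples of whole chromosomes. The ends of chromosomes 7 and 8 were defined after the data were examined, as the first 7 Mb of chromosome 7 and chromosome 8 from 140 Mb on.

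The results, tests, alternatives and the rule for named regions were fixed before the data were examined. The rule took, per ORCA stage and for MeDIP, the 5 peaks with the highest score. It also took the 10 regions in all 3 ORCA lists with the best mean rank, the 5 best in a single stage, the 10 best in all 3 stages with a MeDIP peak, and the 5 densest 1 Mb bins per stage, with ties taken by position. The alternatives were an overlap of 50% of the shorter peak, peaks within 1 kb, the higher-scoring part of each list by its median rank, ORCA lists of equal length, local shifts, the widest 5% of peaks left out, all sequence names, 5 Mb bins and covered bases per bin. A run of narrow peaks was 4 or more peaks of score 100 or more and under 1 kb wide, with neighbours at most 20 kb apart. Leaving out the dense ends of chromosomes 7 and 8, or runs of narrow peaks, was added after seeing the data, as were the differences between MeDIP shares and their weighting to equal peak widths in 6 classes.

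With 1 sample per group no replicate could be left out and no test between stages was run. The location of peaks relative to genes, the genes at peaks and the gene lists planned for these were not run, because an annotation of hg19 was not used here. The 4 inputs were not analysed here. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.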

Results

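ORCA binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in U2OS cells at early, mid and late G1, and methylated DNA was mapped in U2OS cells by methylated DNA immunoprecipitation and sequencing (MeDIP-seq). U2OS is a human osteosarcoma cell line. ORCA, also called LRWD1, is a WD-repeat protein that associates with the origin recognition complex, the complex that marks where DNA replication can begin. In MeDIP, fragments carrying methylated cytosine are pulled down and sequenced, so that a peak marks a stretch rich in methylated CpG. Each of the 3 ORCA samples and the MeDIP sample had a matching input sample, which makes 8 samples in 8 groups of 1 sample. The 4 immunoprecipitated samples came with a peak list, and the 4 inputs were not analysed here. Without replicates, no difference between stages could be set against the spread between samples, and the stages are described side by side. Read depth was not given in the sources used here. Intervals are 95% Wilson intervals and cover counting error only. Peaks are given in hg19 coordinates, and the genes at these positions were not assigned.

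The first question was how many sites ORCA occupied at each stage of G1. On chromosomes 1 to 22 and X, the early list held 10666 ORCA peaks, the mid list 10341 and the late list 1328. The early list was thus 8.03 times and the mid list 7.79 times as long as the late list. The early peaks covered 8.59 Mb, the mid peaks 8.75 Mb and the late peaks 1.68 Mb. Late peaks were wider, with a median of 950 bp against 593 bp in early and 624 bp in mid G1. The MeDIP list held 74497 peaks that covered 79.1 Mb, with a median width of 832 bp. Keeping only the higher-scoring part of each list left 5333 early, 5170 mid and 664 late peaks, by construction. A list with fewer reads or a stricter calling setting is also shorter, and neither was given in the sources used here. The late list carries a different caller label from the early and mid lists, with no statement of what the label means.

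The highest score, 3100, was shared by 16 early, 16 mid and 10 late peaks, so that the 5 named per stage were taken among these by position. The 5 early peaks named first by score all lay on chromosome 1 between 52838686 and 52854476, were 485 to 887 bp wide and had this score. They belonged to a run of 15 narrow, high-scoring peaks. All 5 overlapped a mid peak, 4 overlapped a late peak and 1 overlapped a MeDIP peak. The first mid peaks lay on chromosome 1 from 236259941 to 236261072, on chromosome 2 from 242838231 to 242839280, on chromosome 5 from 175456493 to 175458561 and from 177239045 to 177240773, and on chromosome 6 from 107389812 to 107392259. Each of these 5 overlapped a peak in both other stages. The first late peaks included the same places on chromosome 1, at 236259834 to 236261098, on chromosome 5, at 177239287 to 177241093, and on chromosome 6, at 107389752 to 107392322. The other late peaks named by the rule lay on chromosome 8 from 579027 to 581412 and on chromosome 9 from 141019964 to 141022395. These 10 mid and late peaks also had a score of 3100. Early peaks with this score also lay on chromosomes 6, 16 and 18.

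The next question was which ORCA sites were shared between stages. Most late peaks coincided with peaks of the earlier stages: of 1328 late peaks, 933 overlapped a mid peak (70.3%, interval 67.7 to 72.7) and 869 an early peak (65.4%, interval 62.8 to 67.9). Between early and mid G1, lists of similar length, 3474 of 10666 early peaks overlapped a mid peak (32.6%, interval 31.7 to 33.5). Of the early peaks, 950 overlapped a late peak (8.91%), and 820 overlapped both a mid and a late peak (7.69%). Of the mid peaks, 3366 overlapped an early peak (32.6%) and 985 a late peak (9.53%).

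Merging the 3 lists gave 17319 ORCA regions. Of these, 7062 were found in early G1 only, 6765 in mid G1 only and 274 in late G1 only. A further 2264 regions were shared by early and mid G1, 106 by early and late G1 and 166 by mid and late G1. In all 3 stages there were 682 regions, 3.94% of the total. Peaks found in a single stage had lower scores than the other peaks of their list: the median score of early-only peaks was 59.98, against 83.1 for early peaks that overlapped another stage. The same medians were 64.6 and 96.2 in the mid list and 59.9 and 74.1 in the late list.

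Sharing was above that of random placements in each comparison. The inputs were not analysed and no regions were filtered out, so sites that would give peaks in any library were not set apart. When the early peaks were placed at random on their own chromosomes 1000 times, a mean of 1.24% overlapped a mid peak, so that the observed share was 26.3 times higher. For the late peaks the fold was 43.7 against early peaks and 48.2 against mid peaks. For early peaks that overlapped both other stages it was 52.2. ORCA peaks cluster along chromosomes, and a local shift of each peak by 50 to 500 kb leaves it in the same part of its chromosome. How much of the clustering such shifts keep was not measured. Against such shifts the folds fell to 3.25 for early against mid peaks, 4.72 and 5.07 for late against early and mid peaks, and 4.53 for early peaks in both other stages. All of these lay outside the range of the 1000 placements or shifts. When peaks within 1 kb counted as shared, the folds over random placement were 17.3 for early against mid peaks and 28.1 and 31.6 for late against early and mid peaks. Among the higher-scoring part of each list they were 43.4, 73.1 and 85.6, and 85.8 for early peaks in both other stages.

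Sharing was higher among peaks of higher score, which were also wider. Among the 2134 early peaks in the highest of 5 equal parts by score, 71.2% overlapped a mid peak (interval 69.3 to 73.1), against 16.0% in the lowest part (interval 14.5 to 17.7). Overlap of early peaks with late peaks went from 28.1% in the highest part to 2.16% in the lowest. In the late list, overlap with mid peaks went from 91.0% to 50.9%. The median width went from 1167.5 bp in the highest to 467 bp in the lowest part of the early list and from 1402.5 to 726 bp in the late list. Among early peaks of 500 to 750 bp, a width class chosen after seeing the data, overlap with mid peaks was 54.1% of 294 peaks in the highest part (interval 48.4 to 59.7) and between 25.4% and 18.7% in the others. These shares depend on the length of the lists. With the early and mid lists reduced to the 1328 highest-scoring peaks, the length of the whole late list, 51.0% of early peaks overlapped a mid peak. A late peak was overlapped by 37.3% of these early peaks and by 39.9% of these mid peaks. Of the late peaks, 38.3% then overlapped an early and 42.2% a mid peak, below the share between early and mid G1, and the folds over random placement were 116 and 126. The fold of early against mid peaks was 112, and that of early peaks in both other stages was 186.

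**Figure D1:**
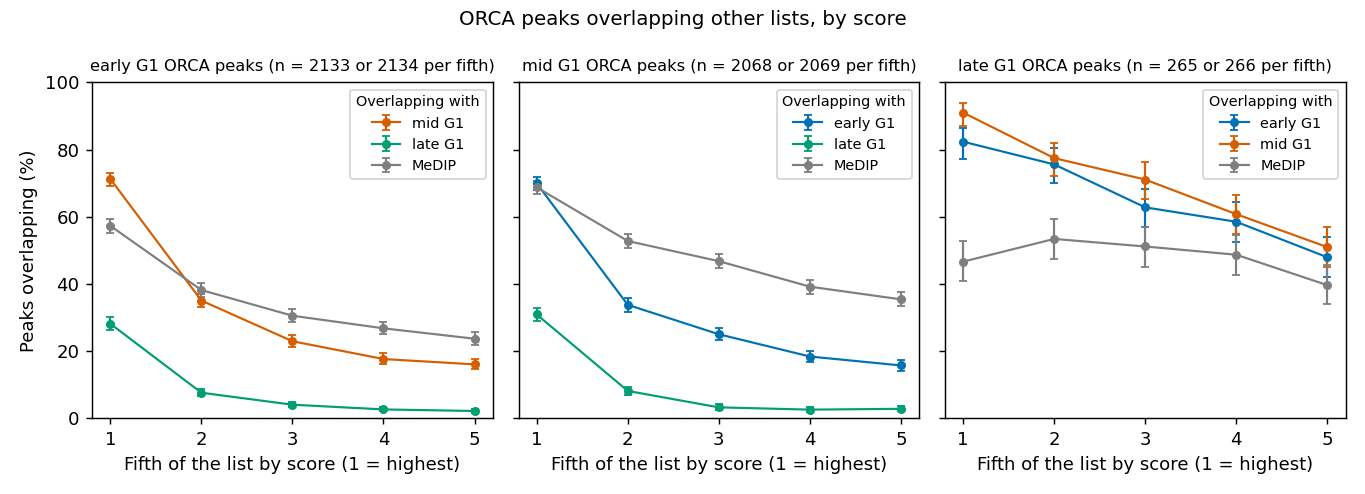
Percent of ORCA peaks that overlap a peak of another list, for 5 equal parts of each ORCA list ordered by score (1 is the highest), with 95% Wilson intervals as bars. Overlap of early with mid peaks falls from 71.2% to 16.0%, and overlap of late with mid peaks from 91.0% to 50.9%.

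The ORCA regions that ranked highest across all 3 stages lay in 6 of 10 cases within 1 Mb of the first or last peak of any list on the chromosome. By mean rank within the lists they were on chromosome 1 from 236259834 to 236261098, chromosome 6 from 107389730 to 107392322, chromosome 16 from 90060419 to 90063658 and chromosome 18 from 94277 to 98059, each with a score of 3100 in the 3 lists. The next were on chromosome 9 from 141019964 to 141024015, chromosome 8 from 578961 to 581552, chromosome 21 from 47233803 to 47236420, chromosome 5 from 177239045 to 177241093, chromosome 22 from 49779136 to 49782623 and chromosome 2 from 242838231 to 242839280. Of these 10 regions, the ones on chromosomes 6, 9 and 18 overlapped a MeDIP peak. Of the 10 named regions of all 3 stages with a MeDIP peak, 1 lay within 1 Mb of such an end. Among the 5 highest-scoring peaks it was 0 in early, 1 in mid and 2 in late G1. Among the 5 regions named per single stage it was 0, 0 and 3. The share over all regions was not computed.

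Regions found in a single stage were ranked within their own list. The early-only regions that ranked first lay on chromosome 16 from 74694642 to 74695458, with a score of 3100, and on chromosome 17 from 40272548 to 40273496, with 2570.5. The next were on chromosome 11 from 79698445 to 79700752, with 2353, and on chromosome 1 from 52866848 to 52867312, with 2151, and from 52850617 to 52851091, with 1758. Of these 5, 4 lay in runs of narrow, high-scoring early peaks, and none overlapped a MeDIP peak. Whether these runs fall on exons, and so whether they are ORCA sites, was not examined. The first mid-only regions had scores from 332 to 548 and lay on chromosome 10 from 134201007 to 134203257, chromosome 4 from 49330289 to 49333820 and from 49133451 to 49137538, chromosome 2 from 45395836 to 45397772 and chromosome 7 from 1148547 to 1150906. All but the one starting at 49133451 overlapped a MeDIP peak. The first late-only regions had scores from 301 to 454. They lay on chromosome 7 from 57187318 to 57188620 and from 56534032 to 56535358, chromosome 19 from 58772981 to 58774305, and chromosome 12 from 133633970 to 133635611 and from 133502177 to 133503615. The one on chromosome 19 overlapped a MeDIP peak.

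The series maps ORCA and methylated CpG in the same cell line, and the next comparison asked how far their sites coincided. A MeDIP peak was found at 3763 of 10666 early ORCA peaks (35.3%, interval 34.4 to 36.2), at 5022 of 10341 mid peaks (48.6%, interval 47.6 to 49.5) and at 636 of 1328 late peaks (47.9%, interval 45.2 to 50.6). Most MeDIP sites had no ORCA peak: 4.60% of the 74497 MeDIP peaks overlapped an early, 6.03% a mid and 0.901% a late ORCA peak. The MeDIP sample had no G1 stage in its labels, and each stage was compared with the same MeDIP list.

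Random placement on the same chromosomes gave a MeDIP overlap of 6.66% for early, 6.77% for mid and 7.77% for late peaks. The observed shares were thus 5.30, 7.18 and 6.16 times higher. Against local shifts by 50 to 500 kb, which gave 17.7%, 19.01% and 23.4%, the folds were 1.999, 2.55 and 2.05. All of these lay outside the range of the placements. Among the higher-scoring part of each list, MeDIP included, the folds over random placement were 8.24 for early, 11.5 for mid and 8.39 for late peaks.

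**Figure D2:**
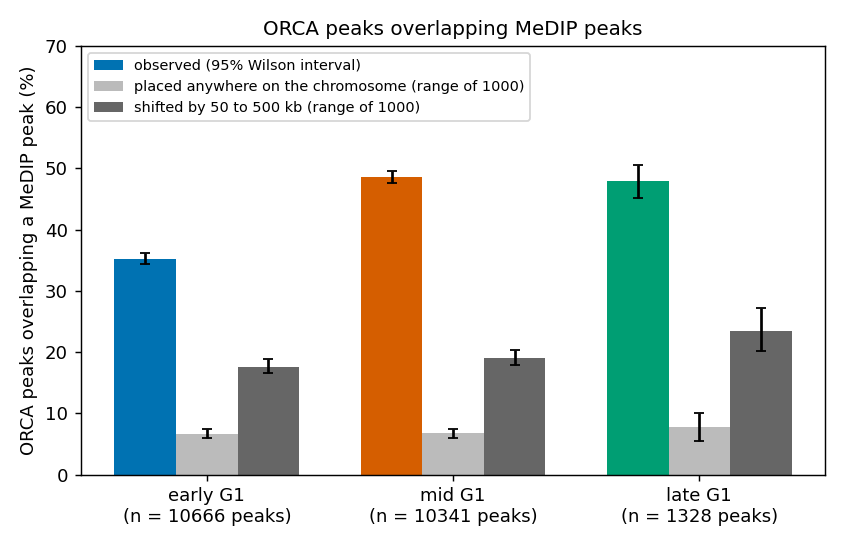
Percent of ORCA peaks that overlap a MeDIP peak at each G1 stage (coloured bars, with 95% Wilson intervals), beside the mean of 1000 random placements on the same chromosome and of 1000 local shifts (grey bars, with the range of the 1000). The observed shares of 35.3%, 48.6% and 47.9% lie above both ranges at each stage.

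The MeDIP share was 13.3 percentage points higher in mid than in early peaks (interval 11.96 to 14.6). The late share was 12.6 percentage points higher than the early share (interval 9.78 to 15.4). The order of late and early did not hold at equal list length: among the 1328 highest-scoring peaks of each stage, 62.3% of early, 71.5% of mid and 47.9% of late peaks overlapped a MeDIP peak. The late list is whole here, while the early and mid lists kept only their highest scores. The early MeDIP share itself went from 57.3% in the highest to 23.7% in the lowest of 5 parts by score. In the higher-scoring part of each list, MeDIP included, the late share was 6.66 percentage points above the early share. With the widest 5% of the peaks of each list left out, MeDIP included, the shares fell to 23.2% of early, 32.1% of mid and 27.9% of late peaks. The mid share was then 8.81 and the late share 4.67 percentage points above the early share. The late share differed from the mid share by -0.672 percentage points (interval -3.52 to 2.18), by -23.6 at equal list length and by -4.14 without the widest peaks. The MeDIP share also depended on peak width. It rose from 21.2% of early peaks under 500 bp to 80.1% of those of at least 3000 bp, from 38.9% to 80.4% in the mid list and from 24.1% to 69.7% in the late list. With the early peaks weighted to the widths of the late peaks, an alternative chosen after seeing the data, the early share was 46.3% and the late share 1.56 percentage points higher. Weighted to the widths of the mid peaks, the early share was 36.7% and the mid share 11.9 percentage points higher.

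The share of regions with a MeDIP peak was highest among ORCA regions of all 3 stages and those shared by early and mid G1. A MeDIP peak was found at 61.4% of the 682 regions of all 3 stages (interval 57.7 to 65.0) and at 58.2% of the 2264 regions shared by early and mid G1 (interval 56.2 to 60.2). It was found at 45.3% of the 106 regions of early and late G1 (interval 36.1 to 54.8) and at 37.3% of the 166 regions of mid and late G1 (interval 30.4 to 44.9). The share was 43.2% in the 6765 mid-only regions (interval 42.1 to 44.4) and 23.01% in the 7062 early-only regions (interval 22.04 to 24.01). It was 19.7% in the 274 late-only regions (interval 15.4 to 24.8). Relative to local shifts the order differed: the fold was 2.87 for mid-only regions, 2.15 for regions of early and mid G1, 2.04 for early and late G1, 1.998 for mid and late G1, 1.95 for all 3 stages and 1.79 for early-only regions. Over random placement it was 6.84, 6.95, 5.39, 4.74, 6.02 and 3.66 in the same order. The late-only regions were above random placement, 2.71 times, but inside the range of local shifts, at 1.36 times their mean. Regions shared by all stages were also wider, with a median of 1826.5 bp against 516 bp for early-only regions.

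The regions of all 3 stages with a MeDIP peak that ranked highest were on chromosome 6 from 107389730 to 107392322, chromosome 7 from 157939223 to 157942048 and chromosome 1 from 161409833 to 161442661, the last of them 32829 bp wide. They were followed by regions on chromosome 20 from 26188478 to 26190737, chromosome 4 from 190987781 to 191014511, chromosome 13 from 113761143 to 113764753, chromosome 7 from 2556186 to 2567671 and from 56440944 to 56443018, and chromosome 8 from 144983843 to 144996346 and from 144996371 to 145020961. All 10 had a MeDIP score of 3100, which the rule favoured, since the mean rank here included the MeDIP rank. Some of these regions were also wide, up to 32829 bp, against a median of 1826.5 bp for regions of all 3 stages. The 5 MeDIP peaks with the highest score, 3233, lay on chromosome 9 from 36985255 to 36986134, chromosome 11 from 62475960 to 62478133, chromosome 13 from 113701572 to 113702821, chromosome 16 from 83998514 to 84000221 and chromosome 21 from 44105880 to 44106692. None of these 5 overlapped an ORCA peak of any stage.

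Along the chromosomes, ORCA peaks were concentrated in the same parts of chromosomes 7 and 8 at each stage. The 5 densest 1 Mb bins of each list lay in the first 7 Mb of chromosome 7 and in chromosome 8 from 140 Mb on. The bin from 1 to 2 Mb of chromosome 7 held 325 early, 290 mid and 62 late peaks. The bin from 2 to 3 Mb held 274, 226 and 37, and that from 5 to 6 Mb held 196, 167 and 33. On chromosome 8, the bin from 144 to 145 Mb held 243 early, 241 mid and 44 late peaks, that from 145 to 146 Mb 197, 213 and 63, and that from 143 to 144 Mb 176, 194 and 21. The median over all 2771 bins was 1 early peak, 1 mid peak and 0 late peaks.

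These ends of chromosomes 7 and 8 together held 2109 early peaks (19.8% of the list), 2031 mid peaks (19.6%) and 330 late peaks (24.8%, interval 22.6 to 27.2). On chromosome 7 the first 7 Mb held 75.7% of the early peaks of the whole chromosome. MeDIP peaks were less concentrated there, with 1.64% of the list in the end of chromosome 7 and 1.11% in that of chromosome 8. These were still 27.7% and 29.0% of the MeDIP peaks of the 2 whole chromosomes. Within these ends 65.5% of early, 67.8% of mid and 77.6% of late ORCA peaks overlapped a MeDIP peak. Elsewhere the shares were 27.8%, 43.9% and 38.1%. Placements within the ends alone were not run, so these shares have no local chance level beside them. Leaving out the ends, an alternative chosen after seeing the data, raised the MeDIP folds against local shifts. They were 2.47 for early, 3.38 for mid and 2.46 for late peaks, against 1.999, 2.55 and 2.05 for the whole lists. In the same alternative the folds of sharing against local shifts rose to 9.49 for early against mid peaks. They rose to 16.3 and 17.7 for late against early and mid peaks, and to 20.8 for early peaks in both other stages.

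**Figure D3:**
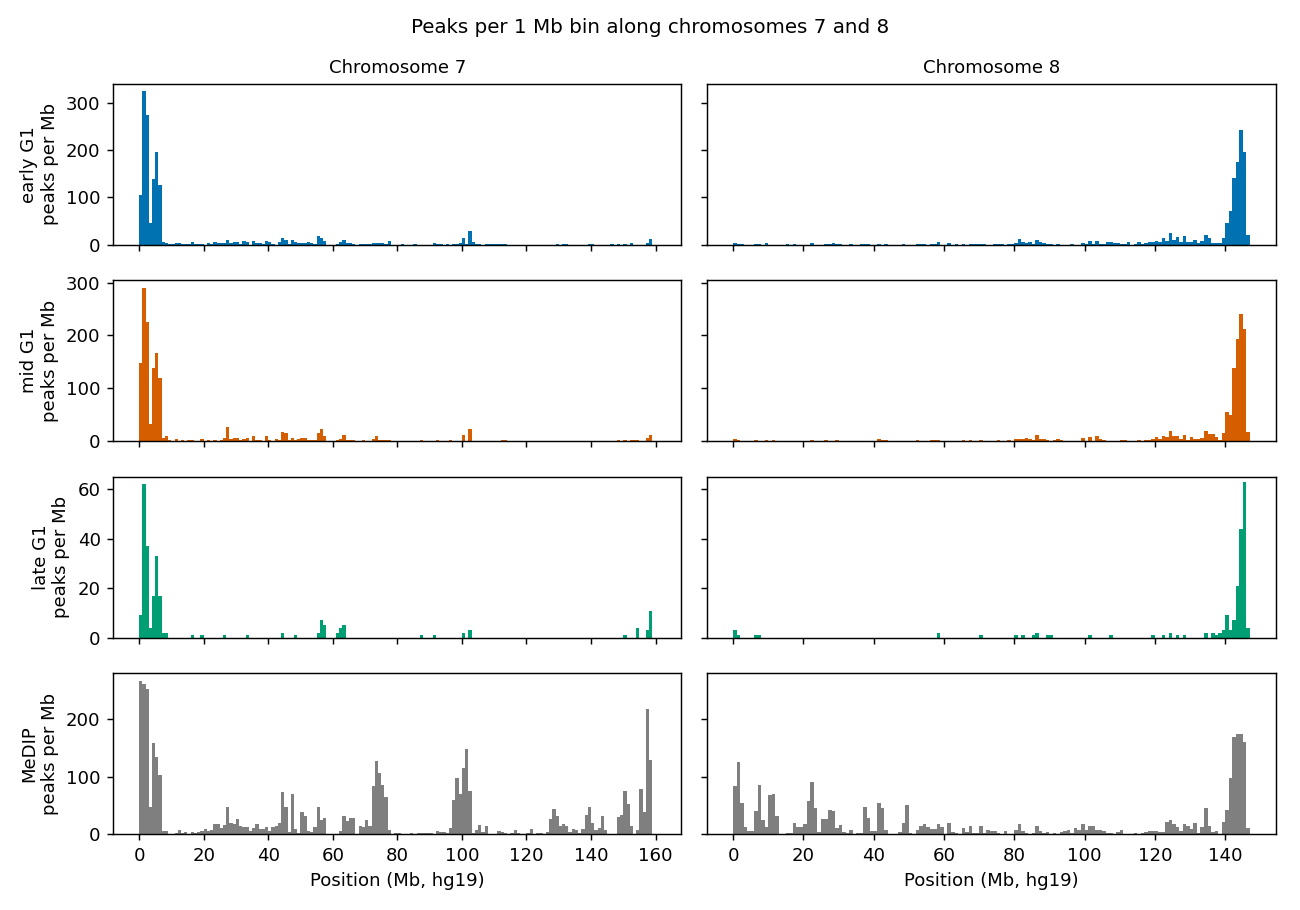
Peaks per 1 Mb bin (vertical axis, separate scale per list) along chromosomes 7 and 8 (horizontal axis, hg19 position in Mb) for the early, mid and late ORCA lists and the MeDIP list. ORCA peaks gather in the first 7 Mb of chromosome 7 and from 140 Mb on in chromosome 8, with up to 325 early peaks in a bin, while MeDIP peaks are spread more widely.

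Whole chromosomes differed as well. In early G1, chromosome 22 had 23.1 peaks per Mb, chromosome 17 had 12.3, chromosome 7 had 11.3 and chromosome 8 had 9.66, against 4.23 per Mb over all chromosomes used. Chromosome X had 0.245 early peaks per Mb, and 26 early, 35 mid and 7 late peaks in total. Chromosome 19 had 98.2 MeDIP peaks per Mb, against 29.5 over all chromosomes, but 3.18 early and 3.33 mid ORCA peaks per Mb, below the 4.23 and 4.10 over all chromosomes. Late peaks there, at 0.945 per Mb, were above their value of 0.526 over all chromosomes. Chromosomes 22 and 17 were dense in both, with 94.7 and 64.9 MeDIP peaks per Mb.

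Across the 2771 bins, Pearson's r of peaks per bin was 0.973 between early and mid G1, 0.869 between early and late G1 and 0.871 between mid and late G1. Spearman's rho was 0.733, 0.470 and 0.482. With MeDIP, r was 0.382 for early, 0.428 for mid and 0.334 for late peaks. Bins are not independent replicates, and these values describe the lists without a test. Without the ends of chromosomes 7 and 8, r was 0.917 between early and mid G1, 0.654 between early and late G1 and 0.676 between mid and late G1.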

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

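The tests of explanations in this part were chosen after the results were seen. Peaks were listed on sequences outside the comparisons, each time more than the 3 counts that a count of 0 allows, which does not show whether they are signal. Chromosome Y held 74 early, 41 mid and 19 late ORCA peaks and 120 MeDIP peaks. The MeDIP list also held 692 peaks on alternative haplotypes, 630 of them on the 7 haplotypes of chromosome 6, and 246 on unplaced or unlocalised sequences. The ORCA lists held no peaks on such sequences.

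The early list held 10 runs of narrow, high-scoring peaks, each with 4 or more peaks of score 100 or more and under 1 kb wide at distances of at most 20 kb. They comprised 83 peaks, among them 10 of the 16 with the highest score. The largest were on chromosome 1 from 52838686 to 52868081 (15 peaks), chromosome 6 from 88311362 to 88376985 (12 peaks) and from 36463445 to 36508137 (10 peaks), and chromosome 16 from 74657727 to 74695458 (10 peaks). Under the same limits the mid list held 9 runs with 39 peaks and the late list 3 runs with 15 peaks. Most mid run peaks were shared: 84.6% overlapped an early peak, against 47.2% of the other mid peaks within the limits. Several mid runs, but no early run, lay in the dense ends of chromosomes 7 and 8, where early peaks were concentrated. The mid share is therefore no direct contrast to the early runs. Of the 10 early runs, 7 had no mid or late peak at any of their 56 peaks. Of the other 3, the run on chromosome 7 had a mid and a late peak at all 5 of its peaks. The run on chromosome 1 had a mid peak at 9 of its 15 peaks and a late peak at 6. A second run on chromosome 16, from 46723464 to 46731713, had a mid peak at 6 of its 7 peaks and a late peak at 5. The larger run on chromosome 16, with 10 peaks, had neither. Extra copies of the run regions in the cell line would raise them at each stage. However, 24.1% of the run peaks overlapped a mid peak (interval 16.2 to 34.3). Of the other early peaks within the same limits of score and width, 69.3% did (interval 65.1 to 73.2). Peaks of a run are not independent, and the 20 run peaks with a mid peak all lay in 3 of the 10 runs. For the 7 runs with no mid or late peak, these values argue against copy number as the whole cause. For the other 3 runs they do not decide. DNA copies of spliced transcripts in the early library, such as a plasmid, could give clusters of narrow peaks. A MeDIP peak was found at 13.3% of run peaks against 41.8% of the others, or 30.5% with these weighted to the narrower widths of the run peaks, but exons were not searched, so that this source and a stage difference in ORCA binding cannot be told apart.

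The ends of chromosomes 7 and 8 held 19.8% of the early ORCA peaks. A high number of MeDIP peaks alone did not go with such density elsewhere. Among the 173 bins with 100 or more MeDIP peaks, the 10 bins in these ends held a median of 186 early ORCA peaks and at least 106. The 163 others held a median of 5 and at most 84. The ends were chosen for their ORCA density, so a higher count there was largely set in advance. The groups were also not matched in MeDIP score, with a median of 434 against 228. Their median number of MeDIP peaks per bin was 170.5 against 142. Bins of the ends with fewer than 100 MeDIP peaks held 45, 47, 71 and 20 early peaks. A role of methylated sites was therefore not excluded. Extra copies of these chromosome ends in the cell line may raise ORCA and MeDIP signal alike. The median MeDIP score of the 10 bins lay at the 87.9th percentile of the 173 bins in the median, with single bins from 39.9 to 100. More methylated DNA would also raise the MeDIP score, so this percentile cannot tell extra copies from methylation. The inputs, not analysed here, could test for extra copies. Apart from methylated sites, no biological explanation was tested.

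The late list was the shortest by a wide margin. Fewer reads or another calling setting in the late sample could shorten a list and would keep its strongest sites. Of the 1328 highest-scoring early peaks, 37.3% overlapped a late peak, against 51.0% that overlapped one of the 1328 highest mid peaks. A loss of ORCA sites late in G1 and a shorter call cannot be told apart from these values, since each stage has 1 sample, the late list has its own caller label and the read numbers were not given in the sources used here.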

How the results depend on the processing

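The 7 folds over random placement, for sharing between stages and overlap with MeDIP, stayed above all placements under each of their 63 alternatives. Their size did not hold and ranged from 1.999 to 186. For late peaks against MeDIP, equal list length repeats the main calculation, because the late list is already the shortest. Of 54 alternatives to the 12 other results, 34 stayed within the limits of the result (1.5 times for a count of peaks, the 95% interval for others), 19 moved it beyond them and 1 turned its direction. The differences between MeDIP shares, the equal widths and the calculations without dense ends or runs of narrow peaks were chosen after seeing the data. The higher-scoring part of each list held 5333 early, 5170 mid and 664 late peaks, by construction. Leaving out the widest 5% of peaks could not take a count of peaks beyond its limit, also by construction. At equal list length, where the late list was kept whole, the MeDIP share of late minus early peaks turned to -14.4 percentage points. Mid minus early was then 9.19 and late minus mid was -23.6. At equal peak widths late minus early was 1.56, mid minus early 11.9 and late minus mid -7.08. With the widest peaks left out these differences were 4.67, 8.81 and -4.14. In the higher-scoring part of each list, late minus early was 6.66 and late minus mid was -7.49. Without the dense ends of chromosomes 7 and 8, mid minus early was 16.0 and late minus mid was -5.79. Pearson's r in 5 Mb bins was 0.989 for early and mid, 0.924 for early and late and 0.925 for mid and late peaks, and with covered bases per bin 0.987 for early and mid peaks. Except for the shorter lists and the equal widths, the cause was not tested. Gene-based alternatives were not run, and no replicate could be left out. Unknown read depth limits all comparisons of list length.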

Other observations

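The observations in this part were chosen after the data were seen, and no explanation of them was tested. ORCA peaks lay close to the ends of several chromosomes at each stage. Within the first 12 kb of a chromosome there were 7 early peaks, on chromosomes 1, 4, 9 and 18, and 7 late peaks on the same chromosomes. The 9 mid peaks there lay on these and on chromosomes 2 and 7. The MeDIP list held 5 peaks there, on chromosomes 1, 17 and 18, and its first peak on chromosome 17 began at 1732. On chromosome 4, peaks from 11168 to 12508 in early, 11210 to 12587 in mid and 11217 to 12574 in late G1 had scores of 418, 963 and 968. At the other end, the last early, mid and late peaks ended within 2 kb of each other on 9 chromosomes: 1, 4, 7, 10, 15, 17, 19, 20 and 21. On 6 of these they lay beyond the last MeDIP peak, on chromosome 1 by 96.3 kb. On 14 of the 23 chromosomes the last MeDIP peak lay beyond the last ORCA peak of each stage.

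Summed over chromosomes, ORCA peaks were also frequent beside the longest peak-free stretch, the part around the centromere. On chromosomes 13, 14, 15 and 22 this was the stretch before the first peak. Within 1 Mb of it lay 512 early peaks (4.80% of the list), 511 mid peaks (4.94%) and 119 late peaks (8.96%, interval 7.54 to 10.6). These were 2.61, 2.68 and 4.67 times the mean of random placements and above all 1000. Such peaks were found on 20 chromosomes in early, 23 in mid and 16 in late G1. MeDIP peaks were below all placements there, with 843 peaks (1.13%) at 0.586 times the mean. Of the late peaks in this zone, 39.5% overlapped a MeDIP peak, as did 38.9% of the mid and 32.03% of the early peaks.

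The few sites found in late G1 alone had an uneven distribution. Of the 274 late-only peaks, 24 lay on chromosome 19 (8.76%, interval 5.96 to 12.7). Of the late peaks shared with another stage, 28 lay there (2.66%, interval 1.84 to 3.81). The chromosome 19 share was 1.71% of early-only and 1.80% of mid-only peaks.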
